A study of Mus musculus with 29 samples.

How the data were processed

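The deposited tables held 13 amygdala libraries and 13 medial prefrontal cortex libraries, 2 regions with 4 groups each. The series described 29 samples in 8 groups. The submitters removed 3 of these, Sus-T without trauma replicate 2 of each region and prefrontal Res-T with trauma replicate 2, and they had no columns, so they were not used here. The design text spoke of 9 mice for the amygdala. Reporter-positive neurons were sorted from enzymatically dissociated tissue punches, and libraries were made with an ultra-low-input kit with ribosomal RNA removal and sequenced with paired ends, as the submitters' protocol notes described.

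Per the submitters' processing notes, reads were converted with bcl2fastq 2.20 and quantified with Salmon 1.2 on GRCm38.p6. The deposited values were treated as a signal in arbitrary units, normalized by the authors before deposit by a method that their notes did not state. After subtracting 1 and taking logarithms, the values centred by gene lacked 1 dimension among the amygdala libraries and 2 among the prefrontal libraries, with the smallest kept share at 0.0208 and 0.0291. The removal of estimated factors on a logarithmic scale would leave such a loss, but whether it was done is not known. The share of the lost dimensions that lay between groups was 0.000 in the amygdala and 0.188 in the prefrontal cortex.

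Library totals of the deposited values ran from 3267967 to 4021272 in the amygdala and from 2095138 to 2444486 in the prefrontal cortex. In amygdala Res-T without trauma they were 3753466, 3974274 and 3795963, in Sus-T without trauma 3267967 and 3440617, in Res-T with trauma 3544036, 3397405, 3381684 and 3558887, and in Sus-T with trauma 4021272, 3473151, 3356421 and 3456604. In prefrontal Res-T without trauma they were 2246413, 2286715, 2133703 and 2343912, in Sus-T without trauma 2269788 and 2106833, in Res-T with trauma 2252624, 2444486 and 2200514, and in Sus-T with trauma 2095138, 2133143, 2123600 and 2417055. The read depth could be estimated from steps between low values only in amygdala Res-T without trauma, at 3711453, 4379324 and 3411218 reads. These libraries had weights of at most 2e-04 in the lost dimension, the other amygdala libraries from 0.0074 to 0.2731. The group thus stood apart in this respect, and it enters the comparisons that called 2706, 610 and 665 genes. Values of a library were identical in every table that held it. There were 9872 genes in the amygdala and 6080 in the prefrontal cortex, with no zeros.

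Gene symbols and coordinates came from GENCODE M21 on GRCm38.p6, matched by the stable gene identifier. The analysis was planned from the labels before the data were examined. The plan foresaw a count-based test for counts and limma otherwise, and limma was used because the unit was a signal. Genes with a mean of at least 1 were kept, which removed none, and values were analysed as log2 of the value plus 1. A linear model with 4 groups was fitted in each region with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation using trend and robust options, 9 residual degrees of freedom and a median prior of 8.32 and 8.4. In each region 5 contrasts were tested. These were Sus-T minus Res-T without trauma, the same with trauma, trauma in Res-T, trauma in Sus-T, and the difference between those trauma effects. All p-values of genes came from limma and were adjusted by the method of Benjamini and Hochberg over all genes of a contrast, with a threshold of 0.05.

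The analysis used 28 lists of genes for synaptic, signalling, metabolic and cell-type functions, written from general knowledge. Lists with at least 4 measured members were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a contrast. Each call was repeated with a correlation estimated from the data, using statmod 1.5.0. Members were counted past the threshold over all genes and when adjusted over the list alone. Cell-type shares were the summed values of a list as percent of the library total.

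Genes were named by a fixed rule. For each contrast it took the 8 rising and 8 falling genes with the smallest p past the threshold, or the 4 smallest where fewer than 4 passed. It added up to 3 members per list past the threshold, the 3 leading members of a called list, and preselected genes, of which Arc, Nr3c1, Fkbp5, Camk2a and Grin2b were measured in the amygdala and Fos and Nr4a1 in the cortex. Predicted genes and pseudogenes were counted but not named unless no other gene was called in that direction.

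The pipeline was tested on simulated data in which 200 genes were changed. At a 2-fold change it recovered from 5 to 53 percent of them and at a 4-fold change from 51 to 90 percent, with 0 wrong signs and from 3 to 8 false calls per contrast. The simulated noise was independent between genes and between libraries, so these rates need not hold for the real libraries. Alternatives planned in advance were quantile normalization, a mean of at least 10, pseudocounts of 0.1 and 10, quality weights, a fit to a pair of groups alone, a block for the replicate number, leaving out each library, an estimated correlation in camera, and fry. Alternatives added afterwards were the missing dimensions as covariates, the logarithm of the value minus 1, leaving out libraries with a quality weight under 0.5, the oligodendrocyte marker mean as a covariate, and, for lists, quantile normalization and leaving out each library. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Isoform-level values and raw reads were not used here.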

Results

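Pyramidal neurons carrying a Thy1-YFP reporter were sorted from the amygdala and the medial prefrontal cortex of mice grouped as Res-T or Sus-T, without or with trauma. In the amygdala 13 libraries were compared over 9872 genes (3 Res-T and 2 Sus-T without trauma, 4 Res-T and 4 Sus-T with trauma). In the medial prefrontal cortex 13 libraries were compared over 6080 genes (4 and 2 without trauma, 3 and 4 with trauma). The labels did not state whether each library came from a separate animal. The design text named 9 mice for the amygdala, fewer than its 13 libraries, so if it counted all of them some amygdala libraries shared an animal. The p-values of genes measure the spread between libraries that remained in the deposited values and treat each library as independent. The dimensions missing from those values lay mostly within groups, so this spread may be too small and the p-values too low. The fit counted 9 residual degrees of freedom without allowing for that loss. Those of lists compare the members with all other genes, and at the preset correlation they treat members as nearly independent. Of 73 list calls 3 held with an estimated correlation. Values are group means with the standard deviation, and log2 changes carry their standard error.

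Amygdala libraries of Sus-T and Res-T mice without trauma differed in genes of the synapse, of protein synthesis and respiration, and of oligodendrocytes. Camk2a, the calcium-dependent kinase of excitatory synapses, rose from 67.0 ± 11.03 to 2311 ± 925.5, which was 32.9-fold (log2 5.04 ± 0.58, adjusted p = 4.3e-05). Bsn, a scaffold of the presynaptic active zone, rose 15.3-fold from 87.1 ± 11.4 to 1381 ± 491.8 (adjusted p = 1.5e-05). Basp1, a growth-cone membrane protein, rose 8.66-fold from 54.9 ± 7.38 to 480.1 ± 15.1 (adjusted p = 7.9e-07), and Mef2c, an activity-dependent transcription factor of neurons, rose 7.48-fold (log2 2.90 ± 0.31, adjusted p = 1.5e-05). Dlgap1, a postsynaptic scaffold, rose 6.08-fold, Gng2 10.8-fold, Vxn 8.60-fold and Snap91 3.57-fold. Ccp110, a centriolar protein, was 4.90-fold lower in Sus-T (5846 ± 368.3 against 1215 ± 342.8, log2 −2.29 ± 0.20, adjusted p = 4.9e-06). Ptprd was 3.70-fold lower, Map7 3.80-fold, Fnbp1 3.72-fold, Sytl2 4.96-fold, Plekhh1 4.78-fold and Slc24a2 3.60-fold lower. In all, limma called 2706 genes, 1223 up and 1483 down, and 921 rises and 1043 falls were at least 2-fold. In 2705 of the 2706 genes the libraries of the groups did not overlap, as did 58.9% of all genes, where chance gives 20%. The Sus-T group held 2 libraries, and without its replicate 1 the count was 1565, with the remaining library assumed to vary like the other groups. With the oligodendrocyte marker mean as a covariate the count was 232.

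Zc3h11a had the largest fall (log2 −6.92 ± 0.30), but this value is uncertain. The symbol belonged to a pair of overlapping gene models on the same strand, among which a quantifier may divide reads. The model ENSMUSG00000116275.1 averaged 370.3 in Res-T and 2.02 in Sus-T, the model ENSMUSG00000102976.6 averaged 335.3 and 428.7, and their sums were 705.6 and 430.7. In the amygdala 4 symbols were shared in this way, the others being Nnt, Ptp4a1 and Sssca1.

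Postsynaptic density genes, which anchor receptors at excitatory synapses, rose as a group in Sus-T without trauma, with 16 of 22 measured members up and none down (17 up when adjusted over the list alone). Dlg4 rose 6.65-fold and Iqsec2 4.77-fold, and the list's median log2 change was 1.92 (adjusted p = 2.5e-10 in limma's camera test, adjusted p = 0.0858 with an estimated correlation). Of 17 genes of synaptic vesicles and release 11 rose, among them Syn1 4.05-fold and Vamp2 2.97-fold, and 1 fell, with the same counts adjusted over the list alone (median 1.15, adjusted p = 1.7e-05, adjusted p = 0.0858 with an estimated correlation). Sodium, calcium and HCN channel genes, which set excitability, rose in 15 of 20 members, including Cacna1a 2.71-fold and Cacna1b 4.52-fold, and in 16 with 1 fall when adjusted over the list alone (median 1.53, adjusted p = 3.3e-07, adjusted p = 0.0858 with an estimated correlation). Of 23 potassium channel genes 11 rose and 3 fell (13 and 4 adjusted over the list alone), with Kcnt2 up 11.7-fold, Kcnma1 up 6.17-fold and Kcna6 2.59-fold lower (median 1.18, adjusted p = 0.000396, adjusted p = 0.145 with an estimated correlation). Ionotropic glutamate receptor genes rose in 9 and fell in 2 of 18 members (10 and 3 adjusted over the list alone), with Gria3 up 4.54-fold, Grik5 up 3-fold and Grin2b, an NMDA receptor subunit, up 4.72-fold (median 1.5, adjusted p = 0.00343, adjusted p = 0.109 with an estimated correlation). Of 9 GABA receptor genes, which carry inhibition, 4 rose (6 adjusted over the list alone), including Gabra4 3.76-fold and Gabbr2 2.57-fold (median 1.33, adjusted p = 0.00402, adjusted p = 0.126 with an estimated correlation). In each of these lists both Sus-T libraries lay above all 3 Res-T libraries in the mean of the list. This does not mark the called lists. Both Sus-T libraries lay beyond all Res-T libraries in every tested list of this comparison, called or not, with few exceptions. These were the glucocorticoid and stress, oligodendrocyte precursor, and endothelial and mural lists.

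Energy and protein synthesis genes were also higher in Sus-T without trauma. Cytosolic ribosomal protein genes rose in 57 of 61 members and in 59 when adjusted over the list alone, with Rpl30 up 3.43-fold (median 1.54, adjusted p = 5.4e-27, adjusted p = 0.126 with an estimated correlation). Their summed share of the library was 0.467 ± 0.0324 percent in Res-T and 1.3 ± 0.0834 percent in Sus-T. Nuclear-encoded oxidative phosphorylation genes, which build the respiratory chain, rose in 30 of 64 members and in 32 adjusted over the list alone, including Ndufa12 2.97-fold and Ndufb8 2.71-fold (median 0.928, adjusted p = 2.1e-11, adjusted p = 0.237 with an estimated correlation). Both measured mitochondrially encoded transcripts rose, mt-Co3 5.63-fold and mt-Nd6 by log2 2.12. In both called lists the 2 Sus-T libraries lay above all Res-T libraries.

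Markers of myelinating cells moved the other way in the amygdala without trauma. Oligodendrocyte markers fell in 16 of 18 members (18 adjusted over the list alone), among them Opalin, 5.27-fold lower (1467 ± 223.9 against 283.0 ± 91.4), Apod, 4.03-fold lower, and Fa2h, 3.88-fold lower (median −1.79, adjusted p = 3.4e-11, adjusted p = 0.126 with an estimated correlation). These markers made up 6.58 ± 0.584 percent of the library in Res-T and 2.48 ± 0.672 percent in Sus-T. Astrocyte markers rose in 7 of 15 members with the same count adjusted over the list alone, including Slc1a2, a glutamate transporter, 4.26-fold and Mlc1 3.55-fold (median 0.903, adjusted p = 0.000396, adjusted p = 0.348 with an estimated correlation), and made up 0.486 ± 0.0976 percent against 1.69 ± 0.719 percent. All 5 microglia and macrophage markers rose, with Tmem119 up 5.13-fold (median 1.42, adjusted p = 0.00815, adjusted p = 0.237 with an estimated correlation), from 0.0128 to 0.0383 percent of the library. Pyramidal neuron markers rose in 4 of 7 members, the same adjusted over the list alone, with Camk2n1 up 8.97-fold (median 0.993, adjusted p = 0.00631, adjusted p = 0.0858 with an estimated correlation). They made up 0.0455 ± 0.00521 percent of the library in Res-T and 0.131 ± 0.0058 percent in Sus-T. Whether the synaptic genes rose beyond the share of neuron RNA in the libraries was not tested. Of 4 sex-linked transcripts 3 from the Y chromosome fell, with Ddx3y 2.04-fold and Uty 1.95-fold lower (median −0.904, adjusted p = 0.0243, adjusted p = 0.237 with an estimated correlation). In these lists both Sus-T libraries lay beyond all 3 Res-T libraries. The astrocyte call ended without Sus-T replicate 3 (adjusted p = 0.0525) and the sex-linked call without Sus-T replicate 1 (adjusted p = 0.0516).

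Genes of activity and plasticity were higher in Sus-T without trauma in part. Of 9 activity-regulated genes 4 rose, with the same count adjusted over the list alone, among them the early transcription factors Egr3 (3.93-fold, log2 1.98 ± 0.53) and Nr4a2 (4.37-fold), while Arc had log2 0.47 and did not pass (adjusted p = 0.267). The list had a median of 1.66 (adjusted p = 0.00631, adjusted p = 0.282 with an estimated correlation). Of 39 genes of actin and dendritic spine remodelling 13 rose and 8 fell (14 and 8 adjusted over the list alone), with Tiam1, a Rac activator, up 5.29-fold and Efnb3 5.70-fold lower (median 0.456, adjusted p = 0.0297, adjusted p = 0.126 with an estimated correlation). Neurotrophin signalling genes rose in 8 and fell in 3 of 17 members (9 and 3 adjusted over the list alone), with Mef2c among the risers (median 0.567, adjusted p = 0.00821, adjusted p = 0.126 with an estimated correlation). In these 3 lists both Sus-T libraries lay above all Res-T libraries, but the actin call ended without Res-T replicate 1 (adjusted p = 0.0651) or Sus-T replicate 1 (adjusted p = 0.0569).

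The glucocorticoid receptor gene Nr3c1 was 1.55-fold lower in Sus-T amygdala without trauma (1335 ± 108 against 864.2 ± 111.8, adjusted p = 0.0213), while its cochaperone gene Fkbp5 had log2 1.32 and did not pass (adjusted p = 0.129). In the list of glucocorticoid and stress signalling 1 of 9 genes rose, Adcyap1r1 by 2.30-fold, and 2 fell, Errfi1 being 1.80-fold lower (log2 0.13 with the oligodendrocyte covariate), with the same counts adjusted over the list alone. Its median was −0.132, its mean 0.135 and its camera direction up (adjusted p = 0.969). Endocannabinoid genes rose in 4 of 12 members, including Mgll 3.04-fold and Dagla 4.05-fold (adjusted p = 0.21 for the list), and metabotropic glutamate receptor genes in 2 of 4, Grm5 4.21-fold and Grm4 5.76-fold (adjusted p = 0.234), with the same counts adjusted over each list alone. Heat shock and dissociation stress genes rose in 2 of 14 members, Hspe1 1.87-fold and Hspb1 7.02-fold, and in 0 when adjusted over the list alone (adjusted p = 0.353). Chromatin regulators rose in 3 and fell in 5 of 36 members (3 and 3 adjusted over the list alone), with Kat2b 4.74-fold lower (log2 0.081 with the oligodendrocyte covariate), Tet1 2.14-fold lower and Hdac4 up 1.83-fold (adjusted p = 0.33). Of 5 GABAergic interneuron markers Erbb4 was 1.66-fold lower (list adjusted p = 0.811), and of 5 markers of striatal and central amygdala neurons none passed (adjusted p = 0.234). Oligodendrocyte precursor markers rose in 1 and fell in 1 of 5 members, Pdgfra up 3.52-fold and Enpp6 7.51-fold lower, and in 2 and 1 adjusted over the list alone, with a median of 0.678, a mean of −0.0118 and the camera direction up (adjusted p = 0.811). Endothelial and mural cell markers rose in 2 and fell in 1 of 9 members, with Col1a2 up 7.66-fold and Kdr 7.27-fold lower (adjusted p = 0.58), and Kdr turned to log2 1.54 with the oligodendrocyte covariate. Too few members were measured to test monoamine and acetylcholine receptors (1, log2 1.34) and ependymal, choroid and blood markers (2, median −0.521).

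**Figure D1:**
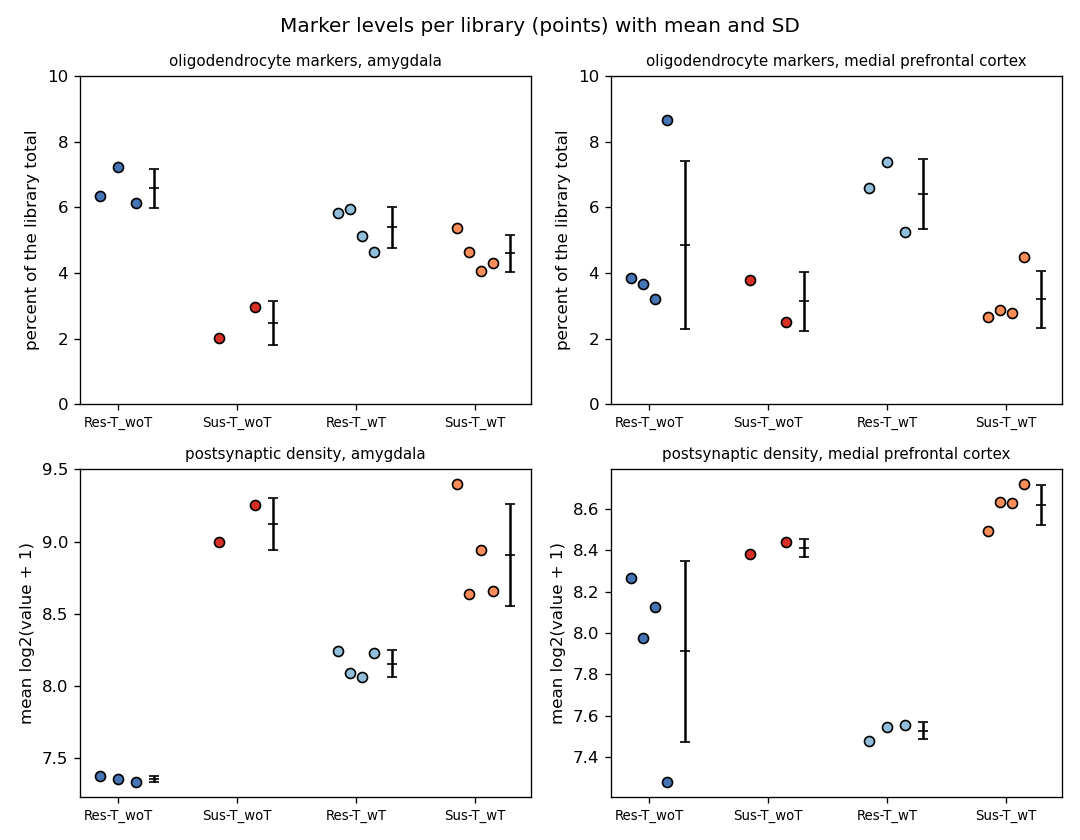
Oligodendrocyte markers as percent of the library total (top) and the mean log2 value of postsynaptic density genes (bottom) in the amygdala (left) and the medial prefrontal cortex (right). Points are libraries in the 4 groups, and bars give the mean and standard deviation, for example 6.58 ± 0.584 percent in amygdala Res-T without trauma.

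With trauma, amygdala libraries of Sus-T and Res-T mice still differed in groups of synaptic genes, although no gene passed on its own. Postsynaptic density genes, the scaffold of excitatory synapses, were higher in Sus-T as a group (median log2 0.667, adjusted p = 1.5e-11, adjusted p = 0.0445 with an estimated correlation), and 11 of 22 rose when adjusted over the list alone. Ionotropic glutamate receptor genes (median 0.377, adjusted p = 4.9e-06, adjusted p = 0.0445 with an estimated correlation, 6 up adjusted over the list alone) and sodium, calcium and HCN channel genes (median 0.577, adjusted p = 2.1e-07, adjusted p = 0.0445 with an estimated correlation, 9 up adjusted over the list alone) were higher too. Of the calls made for the 28 lists in all comparisons, these 3 were the only ones that held with an estimated correlation, and in each all 4 Sus-T libraries lay above all 4 Res-T libraries. This separation does not mark the called lists. Pyramidal neuron markers, which had no call here, were apart in the same way (mean log2 7.77 ± 0.18 in Res-T and 8.23 ± 0.19 in Sus-T). In the 3 lists that held, members closest to the threshold were Kalrn, a spine-forming exchange factor, Sipa1l1 (log2 1.23), Ppp1r9b (1.24) and Cacna1a (0.84). Bsn had 275.6 ± 93.9 in Res-T and 905.0 ± 409 in Sus-T (log2 1.66 ± 0.30, adjusted p = 0.0724) and Camk2a log2 1.94 ± 0.45 (adjusted p = 0.118).

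Further gene groups differed between Sus-T and Res-T amygdala with trauma at the preset correlation. Genes of synaptic vesicles and release had a median log2 change of 0.389 (adjusted p = 0.000239, adjusted p = 0.163 with an estimated correlation) and 6 were up adjusted over the list alone, with Syn1 at log2 0.74. Potassium channel genes had 0.479 (adjusted p = 5.8e-05, adjusted p = 0.17 with an estimated correlation) and 7 up adjusted over the list alone, with Kcnt2 at log2 1.49. Each of these lists had all 4 Sus-T libraries above all Res-T libraries. Neurotrophin signalling had a median of 0.185 (adjusted p = 0.0118, adjusted p = 0.17 with an estimated correlation, 3 of 4 libraries apart) with Crtc1 at log2 0.62, and cytosolic ribosomal proteins 0.332 (adjusted p = 1.6e-09, adjusted p = 0.463 with an estimated correlation, 2 of 4 libraries apart) with Rpl37 at log2 0.86. Markers of striatal and central amygdala neurons had 0.769 (adjusted p = 0.015, adjusted p = 0.245 with an estimated correlation, 3 of 4 libraries apart), with Rgs9 at log2 1.05. Astrocyte markers had 0.476 (adjusted p = 4.2e-05, adjusted p = 0.428 with an estimated correlation, 2 of 4 libraries apart) with Slc1a2 at log2 1.25, and oligodendrocyte markers −0.215 (adjusted p = 0.00788, adjusted p = 0.513 with an estimated correlation, 2 of 4 libraries apart) with Fa2h at log2 −0.67. Oligodendrocyte markers made up 5.39 ± 0.616 percent in Res-T and 4.60 ± 0.563 percent in Sus-T, and astrocyte markers 0.755 ± 0.230 and 1.35 ± 0.487 percent. Without Res-T replicate 2 the neurotrophin, striatal and oligodendrocyte calls ended (adjusted p = 0.0575, 0.138 and 0.218). The striatal call also ended without Sus-T replicate 1 or 3 (adjusted p = 0.0721 and 0.0502) and the oligodendrocyte call without Sus-T replicate 4 (adjusted p = 0.0743).

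Fbxl16, an F-box protein of neurons, came closest to passing (232.0 ± 17.9 in Res-T and 1063 ± 742.6 in Sus-T, log2 1.97 ± 0.31, adjusted p = 0.0534), followed by Rap1gap2 (log2 1.98 ± 0.32), Psd (1.89 ± 0.34), Adamtsl1 (−0.93), Shroom3 (−1.46), Tubb4a (−0.78) and Ldlrad3 (−0.79). Arc (log2 −0.23), Fkbp5 (0.16), Nr3c1 (0.02) and Grin2b (1.32) did not pass either. Limma called 0 of 9872 genes and 1142 had an unadjusted p under 0.05, while 5.75% of all genes had groups that did not overlap, where chance gives 2.86%. Calls appeared after quantile normalization, with a mean of at least 10 and with 10 added before the logarithm (2 each), with quality weights (36), without the library of low weight, Res-T with trauma replicate 2 (12), and with the oligodendrocyte covariate (11). Leaving out Sus-T with trauma replicate 1, 2 or 4 gave 1, 5 and 11.

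**Figure D2:**
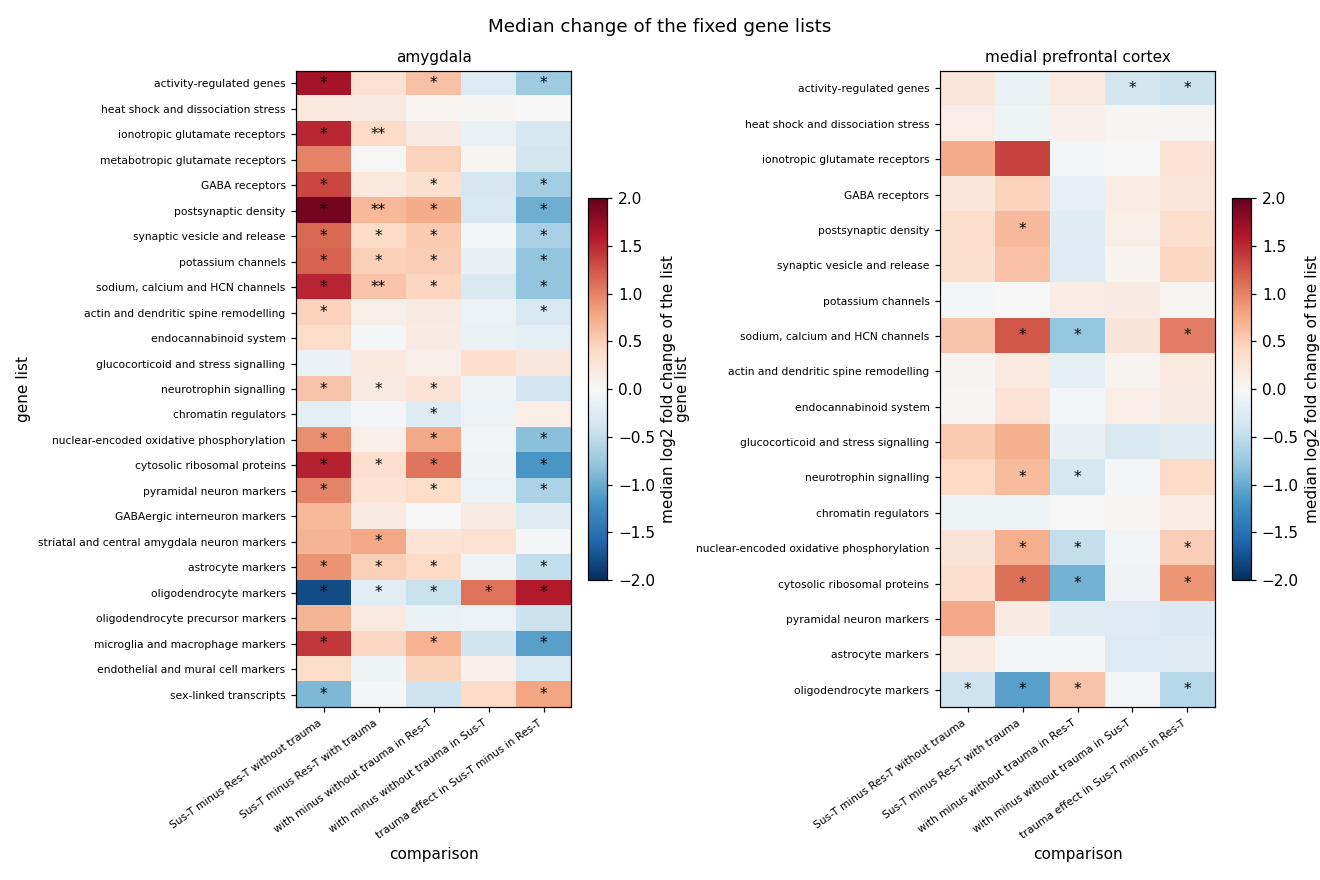
Median log2 change of each gene list (vertical axis) in each comparison (horizontal axis), with the amygdala on the left and the medial prefrontal cortex on the right. Colours run from −2 to 2, with marks for lists under an adjusted p of 0.05 at the preset correlation and also with an estimated correlation, such as postsynaptic density at 0.667 in the amygdala with trauma.

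Trauma in Res-T mice went with higher synaptic and ribosomal transcripts in the amygdala libraries. Basp1, the growth-cone membrane protein, rose 3.47-fold from 54.9 ± 7.38 to 194.3 ± 33.3 (log2 1.80 ± 0.20, adjusted p = 0.000444). Syn1, a coat protein of synaptic vesicles, rose 2.67-fold, Ncs1, a neuronal calcium sensor, 4.56-fold, Evl 3.51-fold, Gng2 3.61-fold and Tuba1b 2.50-fold, and Camk2a rose 6.50-fold from 67.0 ± 11.03 to 482.6 ± 251.6 (adjusted p = 0.01). Chd7, a chromatin remodeller, was 2.09-fold lower with trauma (1321 ± 56.9 to 632.0 ± 45.6), and Ccp110 was 2.12-fold, Plekha1 2.03-fold and Map7 1.98-fold lower. Daam1 had log2 −0.92, Prickle1 −1.02 and Ptprd −0.91. Nr3c1 (log2 −0.31), Grin2b (0.95), Arc (0.23) and Fkbp5 (0.13) did not pass.

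Cytosolic ribosomal protein genes rose in 52 of 61 members in Res-T amygdala with trauma and in 59 adjusted over the list alone, with Rps23 up 3.02-fold and Rps13 2.28-fold (median 1.07, adjusted p = 1.1e-41, adjusted p = 0.126 with an estimated correlation). Oxidative phosphorylation genes rose in 21 of 64 members and in 42 adjusted over the list alone, including Ndufb8 2.08-fold and Ndufb9 2.69-fold (median 0.764, adjusted p = 5.5e-22, adjusted p = 0.186 with an estimated correlation). Postsynaptic density genes rose in 8 of 22 members (11 adjusted over the list alone), with Dlgap1 up 2.34-fold (median 0.744, adjusted p = 1.2e-07, adjusted p = 0.126 with an estimated correlation). Vesicle and release genes rose in 7 of 17, the same adjusted over the list alone, with Bsn up 3.02-fold and Rab3c 2.95-fold (median 0.528, adjusted p = 1.2e-06, adjusted p = 0.126 with an estimated correlation). Sodium, calcium and HCN channel genes rose in 3 members and in 6 adjusted over the list alone, with Cacna1g up 4.62-fold (median 0.422, adjusted p = 0.00151, adjusted p = 0.186 with an estimated correlation). Potassium channel genes rose in 6 and fell in 1 (8 and 2 adjusted over the list alone), with Kcnma1 up 2.51-fold (median 0.490, adjusted p = 0.0101, adjusted p = 0.316 with an estimated correlation). In all these lists the 4 libraries with trauma lay above the 3 without, as they did for ionotropic glutamate receptor genes, which had no list call.

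Smaller shifts in Res-T amygdala with trauma concerned pyramidal markers, of which 2 of 7 rose with the same count adjusted over the list alone (median 0.370, adjusted p = 0.00787, adjusted p = 0.126 with an estimated correlation), Mef2c by 2.93-fold. Neurotrophin genes rose in 2 of 17 and in 5 adjusted over the list alone (median 0.271, adjusted p = 0.0471, adjusted p = 0.302 with an estimated correlation). GABA receptor genes (median 0.323, adjusted p = 0.0471, adjusted p = 0.316 with an estimated correlation) and chromatin regulators (−0.259, adjusted p = 0.0132, adjusted p = 0.316 with an estimated correlation) had 0 members past the threshold, Dnmt3a having log2 −0.57. In these 4 lists all 4 libraries with trauma lay apart from those without. Activity-regulated genes had a median of 0.591 (adjusted p = 0.0244, adjusted p = 0.384 with an estimated correlation), with 1 riser, Fosl2, up 2.55-fold. Astrocyte markers had 0.405 (adjusted p = 0.0138, adjusted p = 0.537 with an estimated correlation), with Mlc1 alone past the threshold at 1.91-fold, and microglia markers 0.695 with 0 members past it (adjusted p = 0.0464, adjusted p = 0.384 with an estimated correlation). Oligodendrocyte markers had −0.445 (adjusted p = 0.00124, adjusted p = 0.384 with an estimated correlation) with 0 members past the threshold, Opalin having log2 −0.79, and made up 6.58 ± 0.584 percent without and 5.39 ± 0.616 percent with trauma. In these 4 lists 3 of the 4 libraries with trauma lay apart. With a library left out, the activity, GABA receptor, neurotrophin, astrocyte and microglia calls each ended at least once without Res-T replicates 1, 2 or 3 of either condition or replicate 4 with trauma (highest adjusted p = 0.0734, 0.116, 0.17, 0.0969 and 0.123), and the chromatin call without replicate 2 with trauma (adjusted p = 0.085). Ionotropic glutamate receptor genes rose in 3 members without a list call (median 0.182, adjusted p = 0.249). GABAergic interneuron markers had a median of −0.00717, a mean of 0.254 and the camera direction up (adjusted p = 0.997).

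In Res-T amygdala limma called 610 genes between trauma and no trauma, 326 up and 284 down, and 53.4% of them rose, against 70.6% after quantile normalization. Basp1 was among 600 of the 610 genes whose groups did not overlap, as was the case in 23.1% of all genes, where chance gives 5.71%. The count was 1389 with quality weights, 389 with the missing dimensions as covariates and 924 with the oligodendrocyte covariate. It was 101, 142 and 163 without Res-T replicates 1, 2 and 3 without trauma, and 322 without Res-T replicate 3 with trauma.

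In Sus-T mice trauma went with higher oligodendrocyte transcripts in the amygdala libraries. Apod, a lipid carrier made by oligodendrocytes, rose 2.65-fold from 705.6 ± 261.1 to 1850 ± 473.2 (log2 1.41 ± 0.24, adjusted p = 0.0465), and all 4 libraries with trauma lay above both without. Ypel2 (log2 1.26, adjusted p = 0.0517), Madd (−0.88), Pcnt (−0.79), Snap91 (−0.66) and Mrc2 (−2.49) did not pass. The oligodendrocyte list was the only called list (median 1.08, adjusted p = 4.2e-17, adjusted p = 0.311 with an estimated correlation), with 1 of 18 members up and 15 up adjusted over the list alone, and all 4 libraries with trauma lay above both without. Its share was 2.48 ± 0.672 percent without and 4.60 ± 0.563 percent with trauma. Camk2a (log2 −0.40), Nr3c1 (0.34), Arc (−0.48), Fkbp5 (−1.03) and Grin2b (0.04) did not pass. Limma called 3 genes in this comparison, the others being the Zc3h11a model of uncertain value (log2 6.27) and Gm28635.

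Gm28635, a predicted gene, fell in Sus-T amygdala with trauma (log2 −5.66, adjusted p = 0.000321), from 164.1 ± 91.6 to 2.01 ± 0.150. It is named because its values were seen to lie near the lowest value of the table, and in Res-T its change was −4.88 (adjusted p = 0.000444). The count of 3 genes became 29 after quantile normalization, 17 with a mean of at least 10, 18 with 10 added, 31 without Res-T with trauma replicate 2 and 1 with the oligodendrocyte covariate. It was 1 without Sus-T replicate 1 and 287 without Sus-T replicate 3, both without trauma. Some lists had a median and mean of opposite sign, namely heat shock (0.0214 and −0.0643), vesicle and release (−0.0308 and 0.00697), metabotropic receptors (0.0395 and −0.297) and oligodendrocyte precursors (−0.122 and 0.153).

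The effect of trauma differed between Sus-T and Res-T in the amygdala, and this was tested directly as an interaction. Ccp110, the centriolar protein, had the smallest p on the positive side among models of certain value (log2 2.08 ± 0.25, adjusted p = 0.000967), with means of 5846 and 2768 in Res-T and 1215 and 2397 in Sus-T, without and with trauma. Prickle1, a planar polarity protein, had 1.94 ± 0.25, Unc5c 2.11, Tmem88b 1.99, Plekha1 1.76, Slc24a2 1.69 and Ptprd 1.60. Camk2a had −3.10 ± 0.73 (adjusted p = 0.0236), Mef2c −2.63 ± 0.40, Basp1 −2.29 ± 0.30, Gng2 −2.81, Evl −2.22, Ppm1e −1.95, Tuba1b −1.83, Dlgap1 −1.82 and Snap91 −1.47. Nr3c1 (log2 0.65), Grin2b (−0.92) and Arc (−0.71) did not pass. The Zc3h11a model had 7.52 and is uncertain.

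Oligodendrocyte markers had a more positive trauma effect in Sus-T, with 13 of 18 members past the threshold and 16 adjusted over the list alone, including Opalin (log2 1.99 ± 0.36) and Mal (1.81 ± 0.29), both of myelin (list median 1.59, adjusted p = 6e-12, adjusted p = 0.152 with an estimated correlation). Ribosomal protein genes had a more negative effect in 22 of 61 members and 54 adjusted over the list alone, with Rps20 at −1.64 (median −1.16, adjusted p = 8.9e-25, adjusted p = 0.21 with an estimated correlation). Oxidative phosphorylation genes did so in 9 of 64 and 17 adjusted over the list alone, with Ndufv2 at −1.46 (median −0.839, adjusted p = 2.9e-12, adjusted p = 0.282 with an estimated correlation). Postsynaptic density genes did so in 8 of 22 and 10 adjusted over the list alone, with Dlg4 at −1.72 (median −0.981, adjusted p = 1e-06, adjusted p = 0.152 with an estimated correlation), and vesicle genes in 4 of 17 and 7 adjusted over the list alone, with Bsn at −2.27 (median −0.644, adjusted p = 0.000274, adjusted p = 0.152 with an estimated correlation). Sodium, calcium and HCN channel genes had 1 member past the threshold, Fgf12 at −1.66 (median −0.783, adjusted p = 0.00073, adjusted p = 0.152 with an estimated correlation), and potassium channel genes 3 below and 1 above, with Kcnma1 at −1.79 (median −0.792, adjusted p = 0.0236, adjusted p = 0.339 with an estimated correlation).

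Of the remaining called lists of this interaction, actin and spine genes had 1 member above and 1 below, Efnb3 at 2.21 and Tiam1 at −1.88 (median −0.313, adjusted p = 0.0394, adjusted p = 0.152 with an estimated correlation). Pyramidal markers had Mef2c below (median −0.632, adjusted p = 0.0236, adjusted p = 0.152 with an estimated correlation) and sex-linked transcripts had Ddx3y above at 0.97 (median 0.782, adjusted p = 0.0256, adjusted p = 0.282 with an estimated correlation). GABA receptor genes (median −0.695, adjusted p = 0.0236, adjusted p = 0.272 with an estimated correlation) and activity-regulated genes (−0.705, adjusted p = 0.0236, adjusted p = 0.353 with an estimated correlation) had 0 members past the threshold. The same held for astrocyte markers (−0.486, adjusted p = 0.0314, adjusted p = 0.643 with an estimated correlation) and microglia markers (−1.09, adjusted p = 0.0236, adjusted p = 0.324 with an estimated correlation). Without Sus-T replicate 3 without trauma the calls of activity, GABA receptor, potassium channel, actin, pyramidal, astrocyte and microglia genes ended (adjusted p = 0.0555, 0.116, 0.116, 0.0832, 0.0604, 0.757 and 0.116). The sex-linked and actin calls ended without Sus-T replicate 1 without trauma (adjusted p = 0.052 and 0.0692), and the actin, astrocyte and microglia calls also without other single libraries (highest adjusted p = 0.092, 0.168 and 0.0732). Limma called 665 genes, Ccp110 among them, 470 with a more positive and 195 with a more negative effect in Sus-T, and 70.7% were positive against 57.8% after quantile normalization. The count was 403 with the missing dimensions as covariates and 2 with the oligodendrocyte covariate. It was 340, 340 and 379 without Res-T replicates 1, 2 and 3 and 59 without Sus-T replicate 1, all without trauma.

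In the medial prefrontal cortex without trauma, oligodendrocyte markers were lower in Sus-T than in Res-T as a list with all libraries, and no gene passed. The markers made up 4.85 ± 2.56 percent of the library in Res-T, where replicate 4 had 8.67 and the lowest 3.20 percent, and 3.14 ± 0.899 percent in Sus-T. Without Res-T replicate 4 the list's median was −0.0515 (adjusted p = 0.239), and without Sus-T replicate 3 it turned to 0.0771 (adjusted p = 0.768). Fa2h, which makes myelin lipids, had log2 −1.78 and Mag −0.76, and 1 of 12 members fell when adjusted over the list alone (median −0.421, adjusted p = 0.0185, adjusted p = 0.594 with an estimated correlation, 1 of 2 Sus-T libraries apart). Postsynaptic density genes had a median of 0.350 without a call (adjusted p = 0.0669). Fos, the activity-induced transcription factor, had 3140 ± 1797 in Res-T and 3530 ± 3290 in Sus-T, and Nr4a1 had log2 0.70. The smallest p-values belonged to Copz2 (log2 2.90 ± 0.71), Osbpl6 (2.24), Tpm4 (1.52), Rrs1 (−2.02 ± 0.40, adjusted p = 0.0802), Lcorl (−1.31) and Rasgrp3 (−1.40), none past the threshold. Limma called 0 of 6080 genes, and 630 had an unadjusted p under 0.05, while 14.9% had groups that did not overlap, where chance gives 13.3%. Calls appeared with quality weights (5), with the missing dimensions as covariates (2) and without Res-T replicate 2 (11) or 3 (2) or Sus-T replicate 1 (3) or 3 (53). Potassium channel genes had a median of −0.0287, a mean of 0.138 and the camera direction down (adjusted p = 0.996).

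With trauma, prefrontal libraries of Sus-T mice had higher ribosomal protein, oxidative phosphorylation and postsynaptic density transcripts and lower oligodendrocyte markers than those of Res-T mice. Mef2c, the activity-dependent transcription factor, rose 10.4-fold from 119.7 ± 31.8 to 1248 ± 252.2 (adjusted p = 0.00108). Snhg11, a long noncoding transcript of neurons, rose 6.46-fold from 69.4 ± 11.5 to 467.5 ± 147.5 (log2 2.69 ± 0.33, adjusted p = 0.000874), and Hspe1, a mitochondrial chaperone, rose 8.61-fold from 21.2 ± 9.19 to 179.5 ± 38.0. Smpd3 rose 9.24-fold, St3gal5 7.55-fold, Cit 4.18-fold, Rbfox2, a neuronal splicing factor, 3.91-fold and Ap2a2 2.86-fold. Mast4, a microtubule-associated kinase, was 3.07-fold lower in Sus-T (3086 ± 267.2 against 1013 ± 171.6, log2 −1.62 ± 0.20), as were Prpf39 3.56-fold, Ccp110 2.96-fold (3591 ± 82.4 against 1250 ± 350) and Fnbp1 2.72-fold, and Vmn1r55 had log2 −1.76 and Kif13a −1.08. Fos averaged 3258 ± 570 in Res-T and 1332 ± 257.4 in Sus-T and did not pass (adjusted p = 0.0502), nor did Nr4a1 (log2 0.17). Limma called 1397 genes, 854 up and 543 down, with 641 rises and 310 falls at least 2-fold. Groups did not overlap in 1369 of them and in 40.7% of all genes, where chance gives 5.71%. The median over all genes was 0.147 and −0.012 after quantile normalization, and 61.1% of the calls rose against 52.2% after it. The count of 1397 genes was 2203 with quality weights, 892 with the missing dimensions as covariates and 0 with the oligodendrocyte covariate, where limma left 907 at an unadjusted p under 0.05. It was 624, 924 and 669 without Res-T replicates 1, 3 and 4 and 886 without Sus-T replicate 3.

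Ribosomal protein genes rose in 11 of 13 members in Sus-T cortex with trauma (13 adjusted over the list alone), including Rpl18 4.43-fold and Rps15a 2.87-fold (median 1.10, adjusted p = 3.6e-07, adjusted p = 0.285 with an estimated correlation). Oxidative phosphorylation genes rose in 13 of 40, the same adjusted over the list alone, with Ndufa10 up 4.19-fold and Uqcrb 2.84-fold (median 0.722, adjusted p = 1.1e-05, adjusted p = 0.285 with an estimated correlation). Postsynaptic density genes rose in 4 of 10 (5 adjusted over the list alone), with Dlg3 up 7.86-fold and Iqsec2 4.74-fold (median 0.650, adjusted p = 0.0131, adjusted p = 0.285 with an estimated correlation). Sodium, calcium and HCN channel genes rose in 2 of 7 (5 adjusted over the list alone), with Cacna1c, a calcium channel of neurons, up 7.60-fold (median 1.24, adjusted p = 0.0131, adjusted p = 0.285 with an estimated correlation). Neurotrophin genes rose in 5 of 11 (6 adjusted over the list alone), with Crtc1 up 3.24-fold and Map2k1 2.40-fold (median 0.629, adjusted p = 0.0112, adjusted p = 0.285 with an estimated correlation). Oligodendrocyte markers fell in 7 of 12 (11 adjusted over the list alone), with Mag 2.50-fold and Ermn 2.16-fold lower (median −1.08, adjusted p = 1.1e-05, adjusted p = 0.285 with an estimated correlation), and made up 6.40 ± 1.07 percent in Res-T and 3.19 ± 0.861 percent in Sus-T. In these 6 lists all 4 Sus-T libraries lay apart from the 3 Res-T libraries. They also did so in lists without a call, among them vesicle and release, ionotropic glutamate receptor and actin genes and pyramidal neuron markers. The pyramidal markers made up 0.0553 ± 0.0179 percent of the library in Res-T and 0.105 ± 0.0067 percent in Sus-T.

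Lists without a call in Sus-T against Res-T cortex with trauma also held changed genes. Vesicle and release genes rose in 4 of 8 members, including Nsf, a fusion factor, 4.36-fold (median 0.583, adjusted p = 0.0753), and ionotropic glutamate receptor genes in 2 of 8, Grin3a 5.21-fold and Neto2 4.34-fold, and in 3 adjusted over the list alone (median 1.35, adjusted p = 0.164). Of 8 potassium channel genes 2 rose, Kcnb2 by 15.3-fold, and 1 fell, with a median of −0.00886, a mean of 0.463 and the camera direction up (adjusted p = 0.917). Activity-regulated genes rose in 2 of 12 members, Dusp6 5.66-fold and Homer1 1.83-fold, and heat shock genes in 1 of 10, Hspe1, with a median of −0.0812, a mean of 0.190 and the camera direction down (adjusted p = 0.95). Nlgn2, a scaffold of inhibitory synapses, rose 2.13-fold, Chrna4, a nicotinic receptor subunit, 7.04-fold, and Pdgfra, a precursor marker, 3.29-fold. Of 33 actin and spine genes 6 rose and 3 fell (adjusted p = 0.331), and of 30 chromatin regulators 4 rose and 2 fell (adjusted p = 0.484).

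Trauma in Res-T mice went with lower ribosomal and respiratory transcripts in the prefrontal libraries as groups, and no gene passed. Ribosomal protein genes had a median log2 change of −0.944, with Rps15a at −1.12 and Rpl18 at −1.73, and 12 of 13 fell adjusted over the list alone (adjusted p = 3.5e-11, adjusted p = 0.273 with an estimated correlation). Oxidative phosphorylation genes had −0.483 and 11 of 40 fell adjusted over the list alone (adjusted p = 2.2e-07, adjusted p = 0.434 with an estimated correlation), and sodium, calcium and HCN channel genes had −0.771 with 4 down adjusted over the list alone, Cacnb4 at −0.74 (adjusted p = 0.0136, adjusted p = 0.318 with an estimated correlation). In these 3 lists all 3 libraries with trauma lay below the 4 without. Neurotrophin genes had −0.344, with 2 down adjusted over the list alone and Mef2c at −1.77 (adjusted p = 0.0193, adjusted p = 0.619 with an estimated correlation, 1 of 3 libraries apart). Oligodendrocyte markers had 0.573, with Ermn at 0.62 (adjusted p = 0.00071, adjusted p = 0.648 with an estimated correlation, 0 of 3 libraries apart), and made up 4.85 ± 2.56 percent without and 6.40 ± 1.07 percent with trauma. Without Res-T replicate 3 without trauma the channel, neurotrophin and oligodendrocyte calls ended (adjusted p = 0.0988, 0.107 and 0.0601), and without replicate 4 with trauma the neurotrophin call (adjusted p = 0.064). Snhg11 (log2 −1.78 ± 0.33, adjusted p = 0.105), St3gal5 (−2.16), Smpd3 (−2.21), St18 (1.25), Csf1 (1.05), Edrf1 (1.24), Atp11a (0.80), Fos (0.25) and Nr4a1 (−0.08) did not pass. Limma called 0 genes and 899 had an unadjusted p under 0.05, while 13.1% had groups that did not overlap, where chance gives 5.71%. Calls appeared with quality weights (668), without the libraries of low weight, Res-T without trauma replicates 2 and 4 (186), and without replicate 4 alone (588).

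In Sus-T prefrontal libraries activity-regulated genes were lower with trauma as a list, but this rested on a single library, and no gene passed. Without trauma the list made up 0.904 percent of replicate 1 and 0.246 percent of replicate 3, and with trauma from 0.257 to 0.343 percent. Fos, the activity-induced transcription factor, had log2 −1.01, Jun −0.68, Dusp1 −0.53 and Nr4a1 −0.61. The list had a median of −0.374 (adjusted p = 0.045, adjusted p = 0.847 with an estimated correlation, 0 of 4 libraries apart), and 0 of 12 members passed over all genes or adjusted over the list alone. Without replicate 1 without trauma the median turned to 0.221 (adjusted p = 0.0242), and the call ended without replicate 2, 3 or 4 with trauma (adjusted p = 0.0656, 0.0708 and 0.518). The smallest p-values belonged to Zfp454 (log2 2.35), Phactr4 (1.98), Pcdhga12 (1.18), Lcorl (0.78), Cyb5r1 (−1.99), Piga (−1.65), Clcc1 (−1.09) and Apaf1 (−1.01). Limma called 0 genes, 91 had an unadjusted p under 0.05, and 3 were called without Sus-T without trauma replicate 3. Groups did not overlap in 8.03% of all genes, where chance gives 13.3%.

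The trauma effect in prefrontal libraries differed between Sus-T and Res-T in 5 lists and in no gene. Ribosomal protein genes (median 0.880, adjusted p = 3.4e-08, adjusted p = 0.31 with an estimated correlation) and sodium, calcium and HCN channel genes (1.03, adjusted p = 0.0128, adjusted p = 0.31 with an estimated correlation) had a more positive effect in Sus-T. So did oxidative phosphorylation genes (0.494, adjusted p = 0.000327, adjusted p = 0.6 with an estimated correlation). Oligodendrocyte markers (−0.568, adjusted p = 0.00261, adjusted p = 0.64 with an estimated correlation) and activity-regulated genes (−0.434, adjusted p = 0.0161, adjusted p = 0.6 with an estimated correlation) had a more negative effect. Without Sus-T replicate 1 without trauma the activity list turned to 0.109 (adjusted p = 0.614) and the channel, respiratory and oligodendrocyte calls ended (adjusted p = 0.0589, 0.0589 and 0.326). The activity call also ended without Res-T replicate 1 without trauma or Sus-T replicate 4 with trauma (adjusted p = 0.0545 and 0.0662). Without Res-T replicate 3 without trauma the channel and oligodendrocyte calls ended (adjusted p = 0.0523 each), and without Sus-T replicate 3 without trauma the channel call (adjusted p = 0.0659). Hspe1, the mitochondrial chaperone, had log2 2.51, Snhg11 1.93, Glcci1 1.68, Snrpd1 3.17, Meis1 −3.88, Klf11 −3.33, Trim36 −2.35, Rsbn1 −1.36, Fos −1.27 and Nr4a1 −0.53, none past the threshold. Limma called 0 genes and 371 had an unadjusted p under 0.05. The median over all genes was 0.115 and 0.017 after quantile normalization, and calls appeared without the libraries of low weight, Res-T without trauma replicates 2 and 4 (3), or without replicate 4 alone (12).

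Coordinates on GRCm38.p6 were chromosome 15, 25363277 to 25413764, for Basp1 (ENSMUSG00000045763.8) and chromosome 9, 108096022 to 108190384, for Bsn (ENSMUSG00000032589.14). Mef2c (ENSMUSG00000005583.16) lay on chromosome 13 from 83504034 to 83667080, Camk2a (ENSMUSG00000024617.16) on chromosome 18 from 60925618 to 60988152, and Ccp110 (ENSMUSG00000033904.16) on chromosome 7 from 118712552 to 118737024. Opalin (ENSMUSG00000050121.9) lay on chromosome 19 from 41061710 to 41077113, Snhg11 (ENSMUSG00000044349.15) on chromosome 2 from 158375638 to 158386145, and Mast4 (ENSMUSG00000034751.16) on chromosome 13 from 102732486 to 103334497.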

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

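All tests of this part concern patterns already seen in the comparisons. Their readings were written before each test was run, except that the comparisons of postsynaptic density genes with astrocyte markers were added only after the other tests had been seen. For the tests with the oligodendrocyte marker mean as a covariate, the reading written in advance was that a change staying more than 2 standard errors from 0 would speak against a share of oligodendrocyte RNA as the explanation. All 3 changes met that reading. They were then for a time read as undecided, because the dimensions missing from the deposited values lay mostly within groups (share between groups 0.000 in the amygdala and 0.188 in the prefrontal cortex), and are now read as written. The oligodendrocyte markers still varied together within groups, with a mean correlation of 0.49 in the amygdala and 0.74 in the cortex, where the highest of 1000 random sets of genes had 0.22 and 0.24. This value was computed last, to choose between those readings. The covariate tests therefore speak against the share as a whole cause but do not exclude it. They rest on slopes within groups, where a part of the variation is missing. The share as the cause was predicted to give a slope below 0 by more than 2 standard errors. In the amygdala the slope was 0.24 ± 0.29 for postsynaptic density genes and 0.58 ± 0.36 for ribosomal proteins. In the cortex it was −0.13 ± 0.18 for oxidative phosphorylation genes and −0.37 ± 0.14 for postsynaptic density genes. Of these only the last met that part of the prediction.

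The rise of synaptic genes in Sus-T amygdala without trauma came with a fall of oligodendrocyte markers, so a lower share of oligodendrocyte RNA could raise all other transcripts. With the marker mean as a covariate the postsynaptic density mean went from 1.77 ± 0.20 to 2.15 ± 0.52. This speaks against the share as the whole cause of that rise, by the reading written in advance. The slope within groups was not below 0 (0.24 ± 0.29), so the covariate could not lower the change, which limits the test. The count of called genes went from 2706 to 232 with the covariate, so a part played by the share stays open. In mean log2, postsynaptic density genes rose by 0.79 ± 0.31 more than astrocyte markers, where a fall of oligodendrocyte RNA alone would move them alike. As summed shares of the library the order was reversed. Astrocyte markers went from 0.486 to 1.69 percent, by a larger factor than postsynaptic density genes, from 0.209 to 0.566 percent. The comparison with astrocyte markers thus depends on the measure and does not exclude such a fall. It was added afterwards and rests on 2 Sus-T libraries, whose astrocyte marker mean was 10.41 ± 0.66. Removing a smooth trend with transcript length and GC content kept at least 90.3 percent of each list's median. Such a trend is therefore unlikely as the main source of these medians. Other effects of length or GC content are not excluded, because a gene was given the median over its annotated transcripts. A biological difference remains open as untested, and with 2 libraries in a group no splits by chance were counted.

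For trauma in Res-T amygdala the ribosomal mean went from 1.08 ± 0.23 to 1.33 ± 0.26 with the covariate. This speaks against the share of oligodendrocyte RNA as the whole cause of the ribosomal rise, by the reading written in advance. That reading is weak here, because the slope within groups was above 0 (0.58 ± 0.36) and could only enlarge the rise. The dimension missing from the values lay within groups, where the slope is measured. The postsynaptic density mean went from 0.80 ± 0.17 to 0.90 ± 0.21. By the same reading, applied here afterwards and with the same limit, this speaks against the share as the whole cause there too. The difference of postsynaptic density genes from astrocyte markers (0.43 ± 0.26) decides nothing. Removing the trend with length and GC content kept at least 90.4 percent of each list's median, which speaks against that trend as the main source. Of 35 splits of these libraries only 1, the real grouping, had as many genes (610, highest other 158). This speaks against a grouping by chance but does not exclude it. The 35 splits allow no smaller share, the missing dimension lay within the real groups, and libraries may share animals. A biological difference remains open as untested.

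For Sus-T against Res-T cortex with trauma the oxidative phosphorylation mean went from 0.82 ± 0.19 to 0.68 ± 0.27 with the covariate. This speaks against the share of oligodendrocyte RNA as the whole cause of that rise. No gene passed with the covariate, so a part played by the share stays open. The postsynaptic density mean went from 1.09 ± 0.20 to 0.70 ± 0.21. By the same reading, applied here afterwards, this speaks against the share as its whole cause. The slope within groups was −0.37 ± 0.14, which has the sign predicted for the share as a cause, and the change became smaller. A part played by the share thus stays open for these genes too. The difference of postsynaptic density genes from astrocyte markers (1.13 ± 0.58) decides nothing. Removing the trend with length and GC content kept at least 84.8 percent of each list's median, which speaks against that trend as the main source. Of 35 splits only 1, the real grouping, had as many genes (1397, highest other 0). This speaks against a grouping by chance but does not exclude it. The 35 splits allow no smaller share, and the missing dimensions lay mostly within the real groups. A biological difference remains open as untested.

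For comparisons without called genes the splits decide nothing, because any split reaches a count of 0. Sus-T against Res-T amygdala with trauma had 0 genes in the real grouping and 0 in the highest other split, with all 35 splits at as many. Trauma in Res-T cortex had 0 in the real grouping, which all 35 splits reached. Its highest other split had 878 genes and placed Res-T without trauma replicate 4 with the 3 libraries with trauma, which points to a structure among the samples.

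The trauma effect differed between Sus-T and Res-T in 665 amygdala genes, and each named difference shares the 2 Sus-T libraries without trauma. The named genes were Zc3h11a (7.52), Ccp110 (2.08), Prickle1 (1.94), Plekha1 (1.76), Unc5c (2.11), Tmem88b (1.99), Ptprd (1.60) and Slc24a2 (1.69) on the positive side. On the negative side they were Basp1 (−2.29), Mef2c (−2.63), Gng2 (−2.81), Snap91 (−1.47), Dlgap1 (−1.82), Ppm1e (−1.95), Tuba1b (−1.83), Evl (−2.22) and Camk2a (−3.10). The list medians that differed in the amygdala were 1.59 for oligodendrocyte markers, 0.782 for sex-linked transcripts, −1.16 for ribosomal proteins, −1.09 for microglia markers, −0.981 for postsynaptic density and −0.839 for oxidative phosphorylation. Others were −0.792 for potassium channels, −0.783 for sodium, calcium and HCN channels, −0.705 for activity-regulated genes, −0.695 for GABA receptors, −0.644 for vesicles and release, −0.632 for pyramidal markers, −0.486 for astrocyte markers and −0.313 for actin and spines. In the cortex they were 1.03 for sodium, calcium and HCN channels, 0.880 for ribosomal proteins, 0.494 for oxidative phosphorylation, −0.434 for activity-regulated genes and −0.568 for oligodendrocyte markers.

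Single libraries stood apart from the other 3 of their group in 8 of 146 amygdala tests and 5 of 124 cortex tests, where chance gives about 1 in 20 groups. In amygdala Sus-T with trauma the endocannabinoid mean of replicate 3 was 8.31 (others 7.99 to 8.03), the pyramidal marker mean of replicate 1 was 8.51 (8.11 to 8.17), Basp1 of replicate 2 was 305 (349 to 357) and Ppm1e of replicate 3 was 232 (168 to 176). In amygdala Res-T with trauma Ldlrad3 of replicate 2 was 428 (331 to 343), Pld3 780 (308 to 340) and Tuba1b 1200 (642 to 697), and Nr3c1 of replicate 4 was 1300 (985 to 1040). In cortex Sus-T with trauma the library total of replicate 4 was 2420000 (2100000 to 2130000), Prpf39 of replicate 2 was 309 (189 to 205) and Thbs2 of replicate 1 was 42.4 (8.76 to 11.6). In cortex Res-T without trauma replicate 4 had a neurotrophin mean of 8.51 (9.14 to 9.22) and Ap2a2 at 343 (575 to 595).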

How the results depend on the processing

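Added after the results were seen were the missing dimensions, the value minus 1, the libraries of low weight and the oligodendrocyte covariate, and the cause of a shift in a count was not tested. Quantile normalization gave 2 genes for Sus-T against Res-T amygdala with trauma and 29 for trauma in Sus-T amygdala, a mean of at least 10 gave 2 and 17, and adding 10 gave 2 and 18. Quality weights gave 36 for amygdala with trauma, 1389 for trauma in Res-T amygdala, 5 and 2203 for cortex without and with trauma, and 668 for trauma in Res-T cortex. The missing dimensions gave 389 for trauma in Res-T amygdala, 403 for its interaction, and 2 and 892 for cortex without and with trauma. Without the libraries of low weight (amygdala Res-T with trauma 2 at 0.27, cortex Res-T without trauma 2 and 4 at 0.41 and 0.45) the counts were 12 for amygdala with trauma, 31 for trauma in Sus-T amygdala, 186 for trauma in Res-T cortex and 3 for its interaction. The oligodendrocyte covariate gave 232, 11, 924, 1 and 2 for the amygdala contrasts in order, 0 for cortex with trauma (907 at an unadjusted p under 0.05), and kept 64 of the 235 named calls while adding 12 (76 in all). With it the postsynaptic density change went from 1.77 ± 0.20 to 2.15 ± 0.52 in amygdala without trauma, and from 1.09 ± 0.20 to 0.70 ± 0.21 in cortex with trauma. It turned Errfi1 to 0.13, Kat2b to 0.081 and Kdr to 1.54 in amygdala without trauma and Kat2b to −0.10 in the interaction. Of 73 list calls 3 held with an estimated correlation, 43 with fry (50 called in all), 73 with the missing dimensions (74) and 69 after quantile normalization (81). With each library of a comparison left out, 44 of the 73 held throughout and 3 turned direction. Apart from the oligodendrocyte list itself, 42 of 64 held with the oligodendrocyte covariate (49). With each library left out the counts ran over 1565 to 2096, 0 to 12, 101 to 708, 1 to 287 and 59 to 810 in the amygdala, and 0 to 53, 624 to 1163, 0 to 588, 0 to 3 and 0 to 12 in the cortex, in the same order. Removed libraries could not be put back, and dropping the filter removed nothing, so it is void.

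With a block for the replicate number the counts were 2505, 10, 677, 2 and 463 in the amygdala and 0, 1055, 0, 0 and 0 in the cortex. Of 21 pairs of libraries sharing a number 5 correlated above 0.1 (from −0.33 to 0.35), and 5 were closest to their own number. Of the comparisons with 3 or 4 pairs, 0 had every pair above 0.1. Trauma in Sus-T cortex had 2 pairs, both above 0.1 (0.11 and 0.35) and closest to their own number. The numbers were not taken to pair libraries, which stays open for that comparison.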

Other observations

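The 9 gene families of this part and the test on Mbp and Mobp were chosen only after the results were seen. Vomeronasal and olfactory receptor genes, which serve chemosensation, fell in 69 of 124 members in Sus-T amygdala without trauma, and 1 rose (median −1.63, adjusted p = 1.9e-14 in camera, adjusted p = 0.167 with an estimated correlation). Their library medians were 71.6 ± 12.1 in Res-T and 26.5 ± 6.90 in Sus-T without trauma, and 40.3 ± 5.34 and 35.9 ± 13.9 with trauma. In the cortex with trauma 18 of 36 fell in Sus-T (median −1.33, adjusted p = 4.2e-10, adjusted p = 0.123 with an estimated correlation), from 137.0 ± 24.3 to 48.5 ± 7.82. Whether these values reflect expression of the receptors in the sorted neurons was not tested. Zfp and predicted Gm genes, given below, fell in Sus-T amygdala without trauma as well. Tubulins, the subunits of microtubules, rose in 6 of 11 members and fell in 1 in Sus-T amygdala without trauma (median 1.42, adjusted p = 0.00458, adjusted p = 0.167 with an estimated correlation), from 249.0 ± 30.2 to 586.0 ± 218. In Res-T amygdala 3 rose with trauma (median 0.503, adjusted p = 0.00196, adjusted p = 0.149 with an estimated correlation). In Sus-T amygdala the direction with trauma was down, with 0 members past the threshold (median −0.286, adjusted p = 0.0249, adjusted p = 0.365 with an estimated correlation). The interaction had 4 members below (median −0.828, adjusted p = 0.00102, adjusted p = 0.101 with an estimated correlation).

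Splicing factors of the Srsf, Prpf and Sf3 families fell in 8 of 22 members and rose in 1 in Sus-T cortex with trauma (median −0.524, adjusted p = 0.000949, adjusted p = 0.123 with an estimated correlation), from 496.0 ± 11.6 to 307.0 ± 58.3. Subunits of the vacuolar proton pump, which fills synaptic vesicles and acidifies lysosomes, rose in 5 of 14 there (median 0.518, adjusted p = 0.0146, adjusted p = 0.265 with an estimated correlation) and in 4 of 14 in Sus-T amygdala without trauma (median 0.423, adjusted p = 0.0248, adjusted p = 0.185 with an estimated correlation). Proteasome subunits rose in 8 of 29 and fell in 1 in Sus-T cortex with trauma (median 0.436, adjusted p = 0.0291, adjusted p = 0.265 with an estimated correlation). Zfp genes fell in 46 of 243 and rose in 4 in Sus-T amygdala without trauma (median −0.284, adjusted p = 0.01, adjusted p = 0.167 with an estimated correlation). Predicted Gm genes had a median of −0.695 in Sus-T cortex without trauma with none past the threshold (adjusted p = 9.2e-14, adjusted p = 0.0165 with an estimated correlation). In Sus-T cortex with trauma 30 of 116 fell and 5 rose (adjusted p = 1.9e-06, adjusted p = 0.123 with an estimated correlation), and in Sus-T amygdala without trauma 37 of 220 fell and 7 rose (adjusted p = 0.01, adjusted p = 0.526 with an estimated correlation). Solute carriers rose in 21 and fell in 34 of 173 members in Sus-T amygdala without trauma, and protocadherins rose in 4 and fell in 5 of 44, neither with a call (adjusted p = 0.462 each).

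Mbp (log2 −0.61, adjusted p = 0.121) and Mobp (−0.66, adjusted p = 0.111) were the oligodendrocyte markers that did not pass in Sus-T amygdala without trauma, while the other 16 had a median of −1.88. Transcripts of both genes are carried into myelin processes, so fragments of myelin attached to sorted neurons might keep them when RNA of oligodendrocyte cell bodies is lower. The mean change of Mbp and Mobp exceeded that of the others by 1.14 ± 0.43, but both genes were picked because they had fallen least, so this value restates the observation and tests nothing. The labels give no measure of attached myelin, and the hypothesis stays untested.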
